A study of Mus musculus and Homo sapiens with 107 samples.

How the data were processed

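The series holds 107 samples, of which 12 are the RNA-seq libraries analysed here: 2 human non-small-cell lung cancer lines, A549 and H1299, each with 3 libraries of cells given BRM014 and 3 given DMSO. The other 95 samples, from other assays and cells, were not analysed here. Per the labels' protocols, cells were treated for 12 h with BRM014 at 5 µM or with DMSO, spike-in RNA was added by cell number when the cells were collected, and stranded total RNA libraries depleted of ribosomal RNA were made from 500 ng of RNA. A549 libraries had 9 cycles of PCR and H1299 libraries 8, and the lines were grown in different media, so line, medium and PCR cycles cannot be told apart. The titles and the treatment protocol give DMSO at 0.05%, while the treatment field of the labels gives 0.5%; the values here do not settle which is right. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

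The authors deposited raw counts per gene, as whole numbers with no normalization, in a table for each line. Per the submitters' processing notes, cutadapt 1.14, Bowtie 1.2.2, STAR 2.7.3a, featureCounts and DESeq2 were used with genome build hg38; the role of each tool, the annotation, the strand setting and the versions of the last 2 tools are not given in the sources used here. Without a stated strand setting, counts of overlapping and antisense genes are uncertain. There were 24353 rows for A549 and 24019 for H1299, with 22842 identifiers in both. For A549, 2 of the BRM014 columns share a header, so these 2 libraries carry no replicate number; their counts differed by more than sampling noise, and they entered the tests as replicates of their group. No pair of replicates agreed within sampling noise. The chi-square per degree of freedom, over genes with at least 20 counts, was 2.20 to 11.1 within the groups.

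The tables name genes by Ensembl identifier alone and do not pair the identifiers with symbols. The 2 name tables at hand were for another organism and matched 0 of the identifiers. The 43 gene lists fixed by symbol before the data were examined, and the genes to be named by symbol, were therefore not tested. The rule for named genes took, for each line, the 10 largest rises and the 10 largest falls past the threshold, with a mean of at least 5 CPM (counts scaled to a common library total) and no overlap between treated and control libraries. Because identifiers cannot be named, only the largest rise and the largest fall in each line are printed. Genomic positions are not given for the same reason. Spike-in counts were not used here, because no row is named for them, so total RNA per cell was not measured and all differences are relative to the other genes of a library.

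Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default settings (a count minimum of 10 in a median library and of 15 in total), libraries were scaled with TMM factors, and groups were compared with the two-sided quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. "Changed", "rose" and "fell" refer to genes past this threshold. Standard errors of log2 fold changes were taken as the log2 fold change divided by the square root of its F statistic. Each line was fitted alone. The difference of the responses between the lines (an interaction term) and the difference between the lines in DMSO came from a joined fit of the 12 libraries over the shared identifiers. Overlaps of changed genes were compared with n1 × n2 / N and with Fisher's exact test. Levels are CPM with TMM scaling, as mean ± SD of 3 libraries.

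The steps were tested on simulated data, made from the real means and library sizes with a set of genes changed by known folds. The changed genes were drawn only from those above a minimum mean count, and noise was independent between libraries. Recovery is therefore not known for genes of few counts. The changed genes were also a small share of those simulated, and all others had the same mean in every group. In the real data 37% of the genes changed in A549 and 22% in H1299, 19.5% passed the interaction test and 85.7% differed between the lines in DMSO. Recovery and false calls at such shares were not simulated. In A549, the lowest expression quartile held 391 of the 699 falls and 196 of the 286 rises of at least 2-fold. In A549, 98.5% of the genes changed by 1.5-fold and 100% of those changed by 2-fold were recovered, with 6.57% false calls; in H1299 these were 97%, 98.5% and 5.29%. The interaction recovered 80.6% at 1.5-fold and 98.5% at 2-fold, with 5.58% false calls. The difference between the lines in DMSO recovered 97% and 98.5%, with 6.64% false calls.

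Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, library totals without scaling factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter on low counts, a filter of at least 5 CPM in 3 libraries, tests against a fold of 1.2, a 2-fold minimum, all libraries in a single fit, leaving out each library in turn, and the replicate number as a block. Added after seeing the data were leaving out both unnumbered A549 libraries, a covariate for the first component of the A549 deviations from the group means, thinning the A549 counts to the mean H1299 total in 5 draws, the replicate block with each assignment of the unnumbered A549 libraries to replicates 1 and 2, and cell cycle marker lists by identifier from scran 1.30.0. Lists were tested with camera at a preset correlation of 0.01.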

Results

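The RNA-seq part of the study asked how gene expression in lung cancer cells responds to BRM014, an allosteric inhibitor of BRM and BRG1, the alternative ATPase subunits of the SWI/SNF chromatin remodelling complexes. A549 and H1299, established human lines of non-small-cell lung cancer, were treated for 12 h with 5 µM BRM014 or with DMSO, the solvent, with 3 libraries for each line and treatment. The A549 libraries held 40684360 to 50177678 counts with DMSO and 42417643 to 44910378 with BRM014, and the H1299 libraries 28412113 to 40072734 and 30602193 to 41780029. The 10 most abundant genes took 5.07% to 5.67% of the counts of every library. On the first principal component, which held 93% of the variance, the lines separated, and on the next, which held 2.58%, the BRM014 libraries of each line lay apart from its DMSO libraries.

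In A549, BRM014 changed 5624 of the 15188 genes tested (37%): 2684 rose and 2940 fell. Large changes were mostly falls. Of the genes that changed by at least 2-fold, 699 fell and 286 rose, and of those that changed by at least 4-fold, 164 fell and 44 rose. The median change was a log2 fold change of 0.35 among genes that rose and -0.47 among genes that fell. The gene with the largest fall by the fixed rule, listed as ENSG00000165376, went from 16.9 ± 0.204 CPM with DMSO to 0.801 ± 0.0931 CPM with BRM014 (SD, n = 3), a log2 fold change of -4.40 with a standard error of 0.10 and an adjusted p of 6.81e-11 in edgeR. The gene with the largest rise, ENSG00000153234, went from 1.04 ± 0.137 to 12.7 ± 0.951 CPM, a log2 fold change of 3.60 with a standard error of 0.12 and an adjusted p of 9.06e-10.

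The changes in A549 were spread over all levels of expression. In the expression quartile with the lowest levels (median 0.794 CPM), 12.7% of the genes rose and 15.9% fell, and in the quartile with the highest (median 119 CPM), 18.1% rose and 22.1% fell. Falls of at least 2-fold outnumbered rises in each quartile, by 391 to 196 in the lowest and by 54 to 9 in the highest. A set of 26 genes went from at least 1 CPM with DMSO to under 0.5 CPM with BRM014 and passed the threshold, and 8 genes did the reverse. The division of all changed genes into rises and falls depended on scaling: with library totals in place of TMM factors, 3812 rose and 2451 fell, so 60.9% of the changed genes were higher, against 47.7%. A covariate for the structure that A549 libraries of different treatments shared, added after seeing the data, gave 4165 rises and 3980 falls. The surplus of falls among the genes changed by at least 2-fold was present under each scaling. It was 2.44 falls per rise with TMM and 1.96 with library totals. With that covariate it was 2.38, which is no separate support. The covariate was built from deviations from the group means, so it hardly moves the fold changes and mainly lowers the spread within groups.

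In H1299, BRM014 changed 3296 of 14986 genes (22%): 1392 rose and 1904 fell. Of the genes that changed by at least 2-fold, 242 fell and 47 rose, and 64 fell by at least 4-fold. No gene rose by that much at an adjusted p below 0.05 in edgeR (0 genes), at an unadjusted p below 0.05 (0), in DESeq2 (0) or in limma-voom (0). The median log2 fold change was 0.24 among genes that rose and -0.29 among genes that fell. The largest fall by the fixed rule was that of ENSG00000169247, from 11.6 ± 0.416 to 0.557 ± 0.101 CPM (SD, n = 3), a log2 fold change of -4.37 with a standard error of 0.15 and an adjusted p of 1.46e-22 in edgeR. The largest rise was that of ENSG00000173208, from 11.2 ± 1.09 to 38.7 ± 1.4 CPM, a log2 fold change of 1.77 with a standard error of 0.06 and an adjusted p of 8.48e-22.

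The share of H1299 genes that changed was smaller at low than at high expression. In the lowest quartile (median 1.07 CPM) 3.82% rose and 6.7% fell, and in the highest (median 130 CPM) 10.3% rose and 18.7% fell. The lowest quartile nevertheless held 152 of the falls and 35 of the rises of at least 2-fold. With library totals in place of TMM factors, 2127 genes rose and 1513 fell, so the share of changed genes that were higher moved from 42.2% to 58.4%. Among genes changed by at least 2-fold, falls per rise were 5.15 with TMM and 4.05 with library totals.

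**Figure D1:**
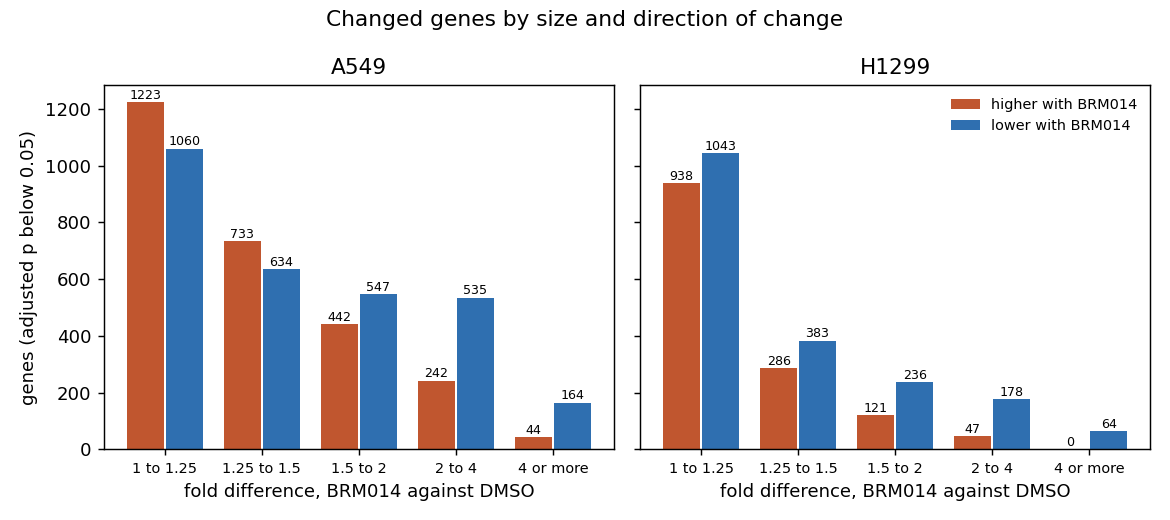
Bars give the number of genes past the threshold in each line (y axis) by the size of the fold difference between BRM014 and DMSO (x axis) and its direction, from edgeR with 3 libraries per group. Rises were as many as 1223 in the smallest class of A549, while falls of 4-fold or more numbered 164 in A549 and 64 in H1299, against 44 and 0 rises.

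The responses of the lines overlapped. Among 13675 genes tested in both lines, 1759 changed in both, where independent lists would share 1113, an odds ratio of 3.08 (95% interval 2.84 to 3.35, two-sided Fisher's exact test p = 8.88e-161, across genes, which are not independent replicates). Of these, 856 genes fell in both lines (310.9 for independent lists) and 589 rose in both (242.9), while 314 changed in opposite directions, 195 of them higher in A549 and lower in H1299 and 119 the reverse (331.2 and 228 for independent lists). For falls of at least 2-fold the overlap was 97 genes, against 4.53 for independent lists, and for rises of at least 2-fold it was 6 genes, against 0.482. Only genes tested in both lines enter here and in the values that follow. They were 333 of the 699 such falls in A549 and 186 of the 242 in H1299. For rises they were 206 of 286 and 32 of 47. Genes that fell by at least 2-fold in A549 had a median log2 fold change of -0.50 in H1299, and 79.9% of them were below 0 there. Genes that fell by at least 2-fold in H1299 had a median of -1.07 in A549, and 92.5% of them were below 0. Across all genes tested in both lines the log2 fold changes correlated with a Pearson r of 0.474 and a Spearman rho of 0.309. The lines share no library, so no common control contributes to this relation. Without a filter on low counts, the Pearson r was 0.141.

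ENSG00000169247, the gene with the largest fall in H1299, fell in A549 as well (log2 fold change -5.13, standard error 0.38, adjusted p = 7.51e-07 in edgeR). Its A549 level was low, with 156 counts over the 3 DMSO libraries and 4 over the 3 BRM014 libraries. The ratio of these counts per total was 37 (95% exact interval 14.2 to 137), and in H1299 it was 20.2 (15.6 to 26.8); the intervals cover counting error only. ENSG00000153234, with the largest rise in A549, rose in H1299 from 3.76 ± 0.202 to 6.15 ± 0.196 CPM (SD, n = 3; log2 fold change 0.70, standard error 0.12, adjusted p = 1.38e-05). ENSG00000165376 had 4 counts over the 6 H1299 libraries and ENSG00000173208 had 6 over the 6 A549 libraries, too few to test in those lines.

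**Figure D2:**
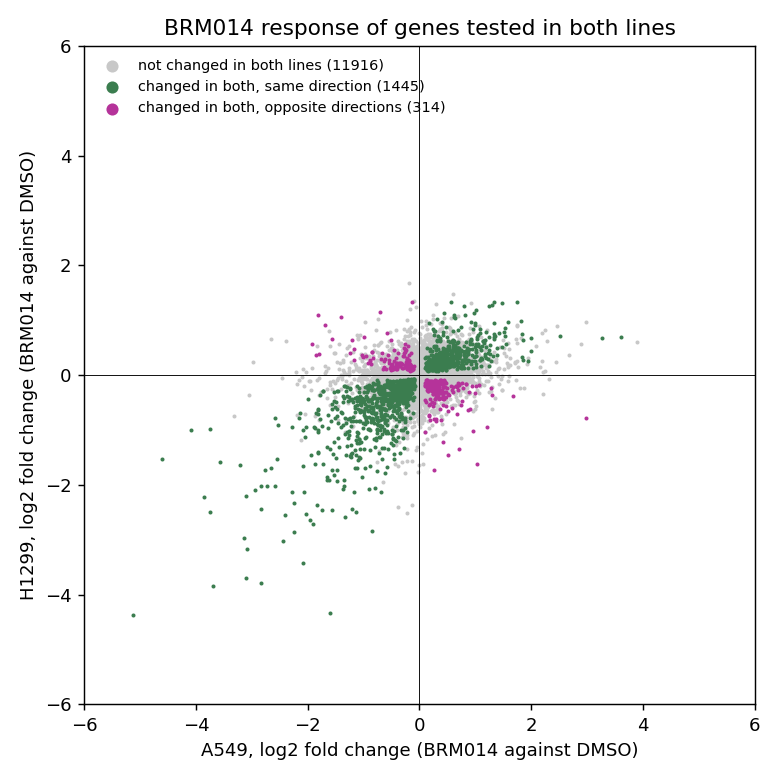
Each point is a gene tested in both lines, placed by its log2 fold change with BRM014 in A549 (x axis) and in H1299 (y axis). The 1445 genes changed in both lines in the same direction lie in the lower left and upper right, and the 314 changed in opposite directions in the other quadrants.

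The response to BRM014 differed between the lines for 3205 of 16466 genes (19.5%) in the test of the line by treatment interaction. The response was more positive in H1299 for 1682 of them and more negative for 1523, and for 477 the difference was at least 2-fold. Of the genes with a different response that were tested in each line alone, 75.7% (2325 of 3072) had the larger absolute change in A549. A549 replicates varied more (common biological coefficient of variation 5.04% against 3.15%), which by itself favours larger absolute changes in A549. The joined fit used a single spread per gene for both lines. It called 6147 genes in A549 and 2555 in H1299, against 5624 and 3296 when each line was fitted alone. All 314 genes that changed in opposite directions passed the interaction test, which their selection from the same libraries made nearly certain. Of the 4480 genes that passed the threshold in A549 or H1299 but not in the other line, 2080 passed it, so for the remainder a difference between the lines was not shown. ENSG00000153234 had the smaller rise in H1299, by a log2 difference of -2.88 (standard error 0.16, adjusted p = 3.95e-12 in edgeR). ENSG00000169247 did not differ by this test (log2 difference 0.78, standard error 0.56, adjusted p = 0.391). With library totals the response was more positive in H1299 for 1358 genes and more negative for 1982, so 40.7% of the genes were in the first group, against 52.5% with TMM. The balance also turned without the unnumbered A549 BRM014 library a, the first of the pair in column order (1775 more positive and 1943 more negative), and with no filter on low counts (1642 and 1671).

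**Figure D3:**
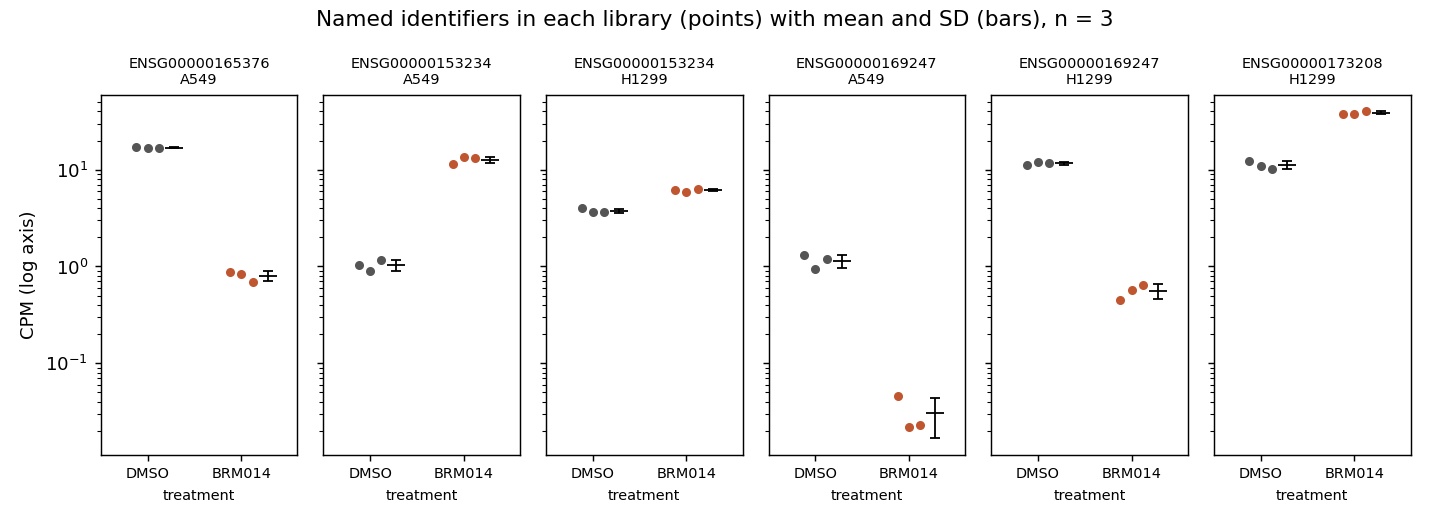
Points give CPM (y axis, log scale) of the 4 named identifiers in each DMSO and BRM014 library (x axis) of the lines in which they were tested, with the mean and SD of 3 libraries beside them. ENSG00000153234 lies at 12.7 ± 0.951 CPM with BRM014 in A549 and at 6.15 ± 0.196 CPM in H1299, from lower DMSO levels in both.

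The lines differed widely without the inhibitor. In DMSO, 14114 of 16466 genes (85.7%) differed, 7071 of them higher in H1299 and 7043 higher in A549. The difference was at least 2-fold for 7152 genes and at least 8-fold for 2491, of which 1204 were higher in H1299 and 1287 higher in A549. ENSG00000165376 and ENSG00000173208 were among the genes with the widest gaps, with log2 differences of -8.82 (adjusted p = 1.2e-20) and 8.21 (adjusted p = 1.75e-20), H1299 minus A549; each rests on 6 or fewer counts in the line with the lower level, so these sizes depend on the fit. Library totals in place of TMM moved the median log2 difference of all genes from 0.02 to 0.24, and 8384 genes were then higher in H1299 and 5823 lower.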

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

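The comparison of replicate spread between the lines, the simulation with no change and the test of the response with independent replicate noise removed were chosen only after the result was seen. The number of genes whose response to BRM014 differed between the lines, 3205, stands out as a difference between groups under the same treatment, by the interaction test. ENSG00000153234 stands out for the same reason, with a log2 difference of -2.88 (H1299 minus A549); over the alternatives it ranged from -2.98 to -2.79 and stayed past the threshold in each.

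More genes passed the threshold in A549 than in H1299 (5624 against 3296). Deeper A549 libraries do not account for this, since after thinning to the mean H1299 total the lowest of 5 draws still gave 1.62 times the H1299 number. Nor do closer replicates, since the common biological coefficient of variation was 1.6 times as large in A549 as in H1299. With thinned libraries, the median absolute log2 fold change of genes at 5 CPM or more was at least 1.64 times that of H1299, above the 1.34 to 1.37 that replicate noise gave in counts simulated with no change. The part of the log2 fold changes shared by library pairs with no library in common leaves out noise that is independent between libraries. Its SD was 1.46 times as large in A549 (0.286 against 0.196), which leaves a larger response there as a hypothesis. Some A549 libraries of different treatments shared deviations (r = 0.701 for DMSO replicate 1 and library a), and their effect on this ratio was not tested.

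Genes changed by at least 2-fold mostly fell in both lines. The scaling methods tried do not account for this: the lowest number of falls per rise over 3 scalings was 1.96 in A549 and 4.05 in H1299. Noise of low counts does not either, because genes at 5 CPM or more in 3 libraries gave 3.21 and 7.42 falls per rise. An upward shift of every gene by 0.22 (A549) or 0.27 (H1299) on the log2 scale would make large rises and falls equal in number, counted without the threshold. A rise of that size in total RNA per cell with BRM014 stays open, since spike-in counts were not used here. It may be a candidate explanation beside loss of expression of individual genes. A drop in total RNA per cell would make the surplus of falls larger instead.

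Other splits of the same libraries were refitted with edgeR. For each line and for the lines in DMSO there are only 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 5624 genes in A549, 3296 in H1299 and 14114 between the lines in DMSO, and the highest of the others gave 0 in each case; at an unadjusted p below 0.05 the real splits gave 6875 and 4827 genes in A549 and H1299, and the highest others 848 and 451. For genes changed in both lines, 1 of 100 combinations of splits, the real one, gave as many as 1759, and the highest other gave 0; since no other split of either line called a gene, the overlap of every other combination is 0 by construction, and these combinations say no more than the 10 splits of each line. For the interaction, 1 of 100 splits drawn within the lines, the real one, gave as many as 3205. The highest other gave 2860, from a split that kept the A549 libraries grouped by treatment and mixed those of H1299. The 84 drawn splits that mixed both lines gave 0 genes, as did every mixed split of either line alone, because mixing puts the treatment effect into the spread within groups. These splits therefore do not decide about chance. Splits that kept only the A549 response gave 1619 to 2860 genes, and those that kept only the H1299 response gave 94 to 211.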

How the results depend on the processing

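The number of changed genes stayed within 1.5 times its value in 18 of 20 alternatives for A549 and 14 of 16 for H1299. It did so in 20 of 22 for the interaction, 24 of 24 for changes in both lines and 18 of 18 in DMSO. The exceptions ask for larger changes: a test against 1.2-fold gave 2442, 776 and 1094 genes in A549, H1299 and the interaction. A 2-fold minimum gave 985, 289 and 477. Neither setting entered the tallies for both lines and DMSO, so these do not show more stability. Leaving out a library at a time gave 4358 to 5971 genes in A549, 2544 to 3397 in H1299, 2662 to 3718 for the interaction, 1466 to 1796 in both lines and 13879 to 14311 in DMSO. The correlation of fold changes was 0.141 with no filter and 0.496 with the 5 CPM filter, which removes genes of few counts, 0.442 to 0.471 without a library, and 0.434 without both unnumbered A549 libraries; the cause was not tested. The 5 CPM filter left 85 rises and 273 falls of at least 2-fold in A549, and 12 and 89 in H1299, with fewer genes tested; the main values were 286 and 699, and 47 and 242. DESeq2 gave 30 and the test against 1.2-fold 23 such rises in H1299. By direction, the test against 1.2-fold gave 910 rises and 1532 falls in A549 (2684 and 2940 in the main test), 163 and 613 in H1299 (1392 and 1904), and 582 more positive and 512 more negative responses in H1299 (1682 and 1523). Library totals raised the rises in H1299 to 2127, and turned the sign of 114 genes called between the lines in DMSO. The 4 named identifiers were followed only in the lines where the main test covered them. There their log2 fold changes kept their sign and passed the threshold in every alternative that kept the gene. Chosen after seeing the data, thinning gave 5356 genes, and the first component of the A549 deviations as a covariate gave 8145, 4165 of them rises. That component is the largest axis of spread between these same libraries, so more calls follow from removing it. Leaving out both unnumbered libraries leaves a single A549 BRM014 library, so no number of genes is given for it.

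With the replicate number as a block, H1299 gave 3272 genes, and both lines gave 1753 with A549 fitted without a block. Same-numbered H1299 libraries deviated from their group means with correlations of -0.086, -0.0224 and 0.0273, so no clear shared deviation was seen. Whether same-numbered libraries were cultured or processed together cannot be read from these values. In A549, DMSO replicate 1 deviated with unnumbered library a (r = 0.701) and both replicates 3 with each other (0.49), but DMSO replicate 2 hardly with library b (0.0756). Blocks were fitted with each assignment of the unnumbered libraries, chosen after seeing the data. With a as replicate 1, A549 gave 7912 genes (4028 rises and 3884 falls), the interaction 4566 and both lines 2206. With a as replicate 2, these were 5519 (2659 and 2860), 3056 and 1746. For these numbers in both lines, H1299 was fitted without a block. Scaling to spike-ins and the tests of gene lists by symbol were not run. Counts of 6 or fewer per line limited 2 named identifiers to the other line.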

Other observations

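The cell cycle lists and their alternatives were chosen after the tables were seen to hold identifiers alone; the predictions for them and for the other tests below were written before their results. Markers of the G1, S and G2/M phases were taken by identifier from a set made on human embryonic stem cells. That set holds ordered gene pairs for each phase and no lists. Each list was made here from genes that stood first and never second in the pairs of its phase, and that no other list shared. Members of each list changed in both directions in each line. In A549, 21 of 84 G1 genes rose and 10 fell, 25 of 93 S genes rose and 21 fell, and 18 of 75 G2/M genes rose and 8 fell, with median log2 fold changes of 0.05, 0.04 and 0.07. In H1299, 11 of 85 G1 genes rose and 13 fell, 12 of 93 S genes rose and 16 fell, and 8 of 76 G2/M genes rose and 12 fell, with medians of -0.02 in each list. Of all genes tested, 2684 of 15188 rose and 2940 fell in A549, and 1392 of 14986 rose and 1904 fell in H1299. A shift in cell cycle phase was tested with camera, which called none of the lists: the smallest adjusted p was 0.142 in A549 and 0.854 in H1299, and with an estimated correlation 0.281 and 0.809. The directional test of fry asks whether a list moves on balance and not whether it moves more than other genes. It called the G2/M list upward in A549 (adjusted p = 0.00827) and the S and G2/M lists downward in H1299 (adjusted p = 0.00315 and 0.00405). Such a direction depends on scaling, and fry was run with TMM factors alone. With library totals the H1299 medians of the S and G2/M lists were 0.013 and 0.017. The result set beforehand as arguing against a shift in phase, no list called by camera, was met in both lines and under every camera alternative run, with 0.0691 as the smallest adjusted p (A549, G1, library totals). The directions of the uncalled lists are not evidence either way: in H1299 the direction that camera gives relative to all other genes was up for G1 and down for S and G2/M with library totals, with the 5 CPM filter, without DMSO replicate 3 and without BRM014 replicate 1. In A549 data simulated with a list raised by 1.2-fold, camera called it in 10 of 10 runs, and smaller shifts were not simulated. In those runs all members rose alike, members had high counts and no other gene changed. In the real A549 data 37% of the genes changed, so the runs do not give the power of the test there. The lack of a call therefore does not exclude a shift in phase.

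Genes with higher expression in A549 than in H1299 fell more often with BRM014. Among 1189 genes at least 8-fold higher in A549, over both treatments, 49.4% fell, against a mean of 12.5% and a highest value of 15.5% in 1000 draws of genes within 2-fold between the lines matched on expression. Their median log2 fold change was -0.31, and 23% of them fell by at least 2-fold, against a mean of 2.25% in the draws. The share that rose, 15%, lay within the range of the draws (13.5% to 20.1%). In H1299, 14.8% of 1032 genes at least 8-fold higher in that line fell, against a mean of 7.89% and a highest value of 10.8% in the draws; their median log2 fold change was 0.01 and the share that rose, 9.98%, lay within the draws (5.52% to 11.1%). A hypothesis that fits these values is that genes expressed in a line-restricted way may depend more on the activity that BRM014 inhibits. Genes are not independent replicates, and the difference of the shares between the lines was not tested.

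Genes in adjacent rows of the tables responded alike. The Spearman correlation of log2 fold changes for genes in neighbouring rows was 0.213 in A549 and 0.163 in H1299, where the highest of 100 shuffled orders gave 0.0219 and 0.0214. Reads shared by overlapping genes could give this for direct neighbours, but the correlation was still 0.0444 in A549 and 0.055 in H1299 at its lowest over distances of 2 to 5 rows, above the highest shuffled values at each of these distances. Weak correlation reached further. At 20 rows apart it was 0.0271 in A549 and 0.0304 in H1299, above the highest shuffled values of 0.0232 and 0.0241. At 50 rows it was 0.0238 in A549, above 0.02, and 0.0193 in H1299, below 0.023. At 100 rows apart it was -0.00423 and 0.00909, not above the highest shuffled values. The sources used here do not say whether the row order follows the genome, so a shared response of neighbouring genes is a hypothesis that these tables alone do not test.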
